A study of Mus musculus with 8 samples.

How the data were processed

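Gene expression was measured in mouse embryonic stem cells on 8 single-colour Affymetrix arrays. The labels put 2 arrays in each of 4 groups: J1 wild-type cells and Rex-1 knockout cells, each with and without leukemia inhibitory factor (LIF). The series text calls the 2 arrays of a group biological replicates. Their titles differ by the letter r, and nothing in the labels says what it marks, so the p-values measure the spread between these arrays. The labels give 12 hours without LIF in a text that is the same for all 8 arrays. The growth text of the knockout arrays titled as lacking LIF mentions added LIF, whereas their titles and treatment text say that it was absent. The titles and treatment text were followed.

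The deposited values are linear signal intensity per probe set. The submitters' processing notes name GCRMA, with no version or role. The mean of each deposited column, leaving out the lowest and highest 2% of probe sets, was 500, the columns had unequal distributions, and no log had been taken, which differs from the usual form of GCRMA values. The step that made the values is therefore not known. The column medians ran from 114.2 to 143.5 and the lowest values from 0.111 to 0.748. No background or detection value was used, so low values carry an unknown share of background. The number of arrays limits the precision.

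The table held 45101 probe sets. The 64 control probe sets were left out, a choice made after the values were seen, which leaves 45037. In the platform annotation 34945 of these have 1 gene symbol, 932 have several and 9160 have none listed here. No gene was named from a probe set with several symbols. Symbols and chromosomes were looked up through the Entrez identifier in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. The arrays name no genome build, so no coordinates are given.

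Intensities were taken to log2 without a pseudocount. Probe sets with a log2 value of at least 4 in at least 2 arrays were kept, which left 43439. limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group over all 8 arrays and eBayes without a trend. Probe sets were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 7 contrasts. Standard errors (SE) come from this fit. Gene lists fixed before the data were examined were tested with camera from limma, with a preset inter-gene correlation of 0.01. Each gene was represented by its probe set of highest mean, over 17837 genes, and p-values were adjusted over 23 lists and 7 contrasts together, 161 tests. An estimated correlation was run beside the preset one. It could raise p-values even where it lay below the preset value, so a call lost with it does not by itself show correlated genes. A list of 3 Zfp42 paralogs had 2 measured genes and was not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

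The rule for named genes was also fixed before the data were examined. It took the called probe sets of largest change, or, with none called, the 5 probe sets of smallest unadjusted p per contrast, and always Zfp42, Triml1, Triml2 and Fat1 where measured. List members named outside that rule were chosen after their values were seen.

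The alternatives fixed before the data were examined covered the filter, normalization, variance prior, arrays in the fit, probe set per gene, threshold, the letter r as a replicate block, and leaving out each array. After these gave few or no calls, 18 further combinations of filter, variance prior and block were tried with knowledge of the data. All 18 are reported in the closing section, and none replaces the planned result. Other alternatives added later are kept control probe sets and, for the lists, quantile normalization, a higher floor, the block, and leaving out each array.

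The letter r was checked as a pairing of arrays. Across the 43439 probe sets the second-minus-first differences of the groups correlated at 0.0497 to 0.198. Since 2 of the 6 pairs of groups lay under 0.1, the letter was not taken as a pairing and the planned fit has no block. The correlations rose with signal, to 0.163 to 0.479 over the 21010 probe sets with a mean log2 of at least 7 and 0.318 to 0.771 over the 6516 with at least 10, values first seen with the settings chosen later. No replicate arrays were copies of each other: at most 0.00222% of their values were identical.

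The fit was tested on simulated data with the measured means, spreads and first-against-second differences, over 43439 probe sets. For the averaged genotype contrast without a block, 0% of the 2-fold, 24% of the 4-fold, 62% of the 16-fold and 78% of the 64-fold changes were called, with 50 simulated changes of each size. For the knockout against J1 with LIF the shares were 0%, 0%, 48% and 68%. For LIF withdrawal in J1 cells they were 0%, 4%, 58% and 66%, and for LIF withdrawal averaged over genotype 0%, 28%, 52% and 80%. The median estimated changes of the simulated probe sets were close to those put in. A simulated shift of -0.5 in the LIF list was called by camera over 17837 genes, with 0 other lists called. This list simulation drew the genes independently and left out the first-against-second differences. It therefore does not show how often lists of correlated genes are called without a shift.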

Results

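Transcript levels were compared between J1 cells, a wild-type mouse embryonic stem cell line, and cells labelled as knockouts of Rex-1, the zinc finger protein encoded by Zfp42. Both were cultured with LIF, the cytokine that holds mouse embryonic stem cells undifferentiated through STAT3, and without it. Each of the 4 groups had 2 arrays, called here the first array and the second array. The median probe set signal ran from 114.2 to 143.5 across the 8 arrays. The second array of the knockout-labelled cells with LIF stood apart, with the median of 143.5, 91.2% of probe sets at or above a log2 of 4 against 85.2% to 87.4% in the others, and a first principal component score of 159.5 against -69.6 to 60.0. The second J1 array with LIF stood apart on the second component, at 126.5 against -56.7 to 72.9, and had the highest log2 mean of the spiked hybridisation controls, 12.54 against 11.51 to 12.15. Replicate arrays differed by a median of 1.01 log2 units at mean log2 levels of 4 to 6. The difference fell to 0.48 at 6 to 8, 0.27 at 8 to 10 and 0.20 at 10 and above.

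The targeted gene was examined first. Zfp42 gave a signal of 20870 ± 3375 (SD, n = 2) in J1 cells with LIF and 17640 ± 505.1 (SD, n = 2) in the arrays labelled knockout with LIF. Without LIF the signals were 19390 ± 1659 (SD, n = 2) and 16930 ± 289.9 (SD, n = 2). The averaged log2 difference, knockout minus J1, was -0.21 (SE 0.16), which limma did not call (adjusted p = 0.985). It was -0.12 with quantile normalization and -0.13 without the second J1 array with LIF, with a range of -0.30 to -0.13 over the arrays left out. The signal was thus among the highest on every array, including those labelled knockout. The position of this probe set relative to the deleted part is not given in the sources used here, and a probe set outside it does not check the labels. Directions below therefore refer to the arrays labelled knockout. Its neighbours Triml1 and Fat1 differed by -0.23 (SE 0.29) and -0.10 (SE 0.16), neither of them called, and Triml2 was not among the annotated probe sets.

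**Figure D1:**
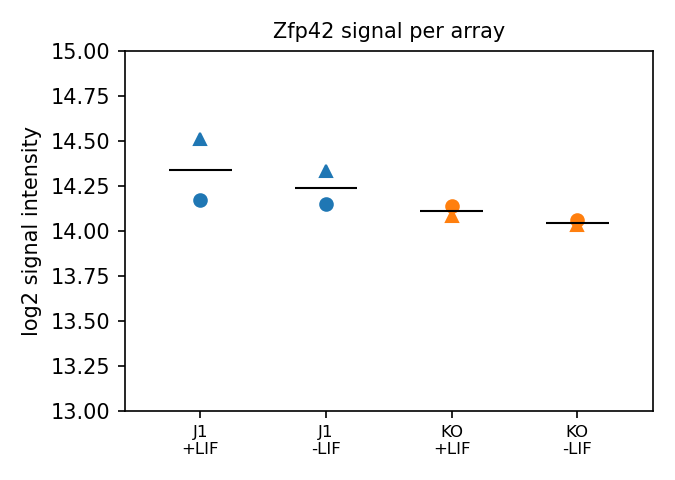
Zfp42 log2 signal intensity (vertical axis, from 13 to 15) in each array of the 4 groups (horizontal axis), with circles for first arrays, triangles for second arrays and bars for group means of 2 arrays. The arrays labelled knockout lie between 14.03 and 14.14, and the J1 arrays between 14.15 and 14.51.

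Withdrawal of LIF was compared in each cell line to ask which genes depend on the cytokine. The fixed list of LIF and STAT3 target genes, 24 of them measured, fell as a list without LIF in both lines by the camera test with a preset correlation. The mean log2 change of the list was -0.63 in J1 cells, with 20 members lower and 4 higher, and -0.56 in the arrays labelled knockout, with 19 lower and 5 higher. Socs3, the feedback inhibitor of this pathway, had values of -2.97 (SE 0.66) in J1 cells and -3.01 (SE 0.66) in the knockout-labelled cells. Averaged over both lines, Socs3 changed by -2.99 (SE 0.47), Bcl3 by -1.78 (SE 0.32), Stat3 itself by -1.13 (SE 0.26), Pim3 by -0.76 (SE 0.18) and Mras by -0.97 (SE 0.24). These 5 averaged changes passed when adjusted over the list alone, with adjusted p from limma between 0.0204 and 0.0370. In the planned fit 0 passed over all probe sets. In each line taken alone 0 members passed over the list. They were chosen after their values were seen. Klf4, a pluripotency factor also on the list, had an averaged change of -0.85 (SE 0.24) and did not pass.

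The list fell in the camera test with the preset correlation, at adjusted p = 7.07e-08 in J1 cells, 2.35e-05 in the knockout-labelled cells and 2.53e-09 on average. With an estimated correlation the adjusted p was 0.673, 0.681 and 0.652. Per array, the mean of the list was lower in all 4 arrays without LIF than in all 4 with it (difference -0.60, exact permutation p = 0.0286, two-sided, the smallest that 4 against 4 arrays can give). Adjusted over the 23 lists that p was 0.657, and since 0.0286 is the smallest raw value, a list passes this adjustment only if most lists reach it together. In J1 cells the change was -0.33 without the second array lacking LIF, with a range of -0.93 to -0.33 over all arrays left out. Leaving out the first array of the knockout-labelled cells with LIF ended the call in those cells, with the list's change there between -0.66 and -0.46 over all arrays left out.

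Genes of the primed epiblast, the state that follows naive pluripotency, formed the list that rose without LIF. Its 20 genes had a mean log2 change of 0.33 in J1 cells, 0.31 in the knockout-labelled cells and 0.32 on average (adjusted p = 7.59e-05 on average by camera). With an estimated correlation the averaged adjusted p was 0.681. Of the 20 genes, 13 were higher on average and 7 lower, and 0 passed when adjusted over the list alone. The averaged values were 1.18 (SE 0.38) for Otx2, 0.95 (SE 0.29) for Zic2, 0.65 (SE 0.16) for Dnmt3a, a de novo DNA methyltransferase, and 0.81 (SE 0.30) for Zic5. Tdgf1, also on the list, had a value of -0.50 (SE 0.16). In J1 cells the call was lost without the second array with LIF or the second array without LIF, where the list's change ranged from 0.10 to 0.57 over the arrays left out. In the knockout-labelled cells it was lost without the first array lacking LIF or the second array with LIF, over a range of 0.14 to 0.47. The averaged change was 0.20 without the second J1 array with LIF.

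The list of 33 measured pluripotency genes had a mean change of -0.15 on average and -0.18 in J1 cells, both called by camera with the preset correlation (adjusted p = 0.0105 and 0.017). With an estimated correlation the adjusted p was 0.719 and 0.727, and both calls were lost when all probe sets of a gene were averaged. The averaged call was lost when any of 4 arrays was left out (range -0.18 to -0.12), the J1 call when any of 3 was (-0.24 to -0.12), and when 3 genes shared with the LIF list were removed both calls were lost, with an adjusted p of 0.103 for an averaged change of -0.10 and 0.164 for -0.12 in J1 cells. The values were -0.42 (SE 0.17) for Esrrb and -0.27 (SE 0.22) for Nanog, neither of them called.

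No single probe set passed for LIF withdrawal. limma called 0 of 43439 probe sets in J1 cells, 0 in the knockout-labelled cells and 0 on average. In 18 settings chosen after seeing the data the averaged count ran from 0 to 24, with every call made with the letter r as a replicate block, and the counts in the single lines were 0. The numbers at an unadjusted p under 0.05 were 1567, 1770 and 1748, against 2172 expected by chance. This planned fit leaves the difference between first and second arrays in its spread. In the later settings with a mean log2 floor of 10 and no trend, the numbers of 6516 were 270, 433 and 560 with the block. Without the block they were 75, 111 and 153. The probe sets of smallest p lay at low signal and were not called. They included Nudt6 (log2 change 2.81, SE 0.27) in J1 cells, Lgr5 (-3.11, SE 0.32) in the knockout-labelled cells, and Cp (-2.17, SE 0.21), Edil3 (1.82, SE 0.19) and Luc7l2 (-2.03, SE 0.22) on average. Across probe sets the LIF changes in the 2 lines correlated at Pearson r = 0.0151 and Spearman rho = 0.0399, with 53.4% of the same sign. Probe sets are not independent replicates, and low-signal probe sets weigh on this value: it was r = 0.415 over the 6516 probe sets with a mean log2 of at least 10, a floor chosen after the data were seen.

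**Figure D2:**
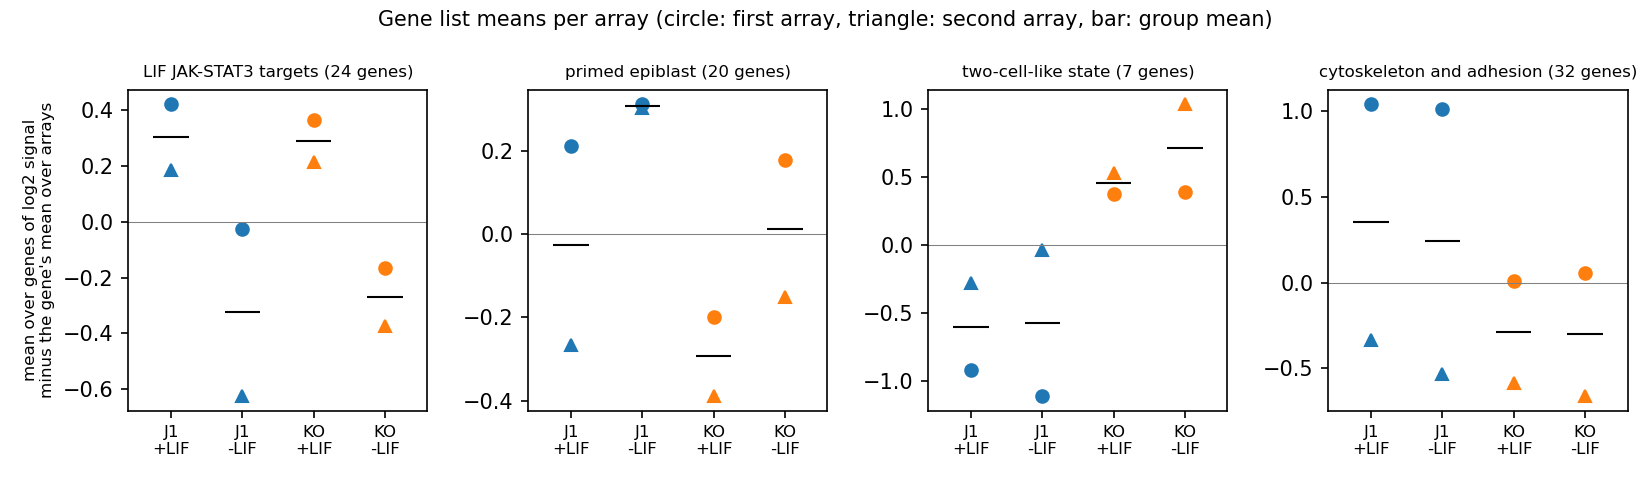
Mean over the genes of 4 lists of the log2 signal minus each gene's mean over all arrays (vertical axis, log2 units), per array in the 4 groups (horizontal axis), with circles for first arrays, triangles for second arrays and bars for group means. The LIF list is lower in every array without LIF (difference -0.60), the two-cell-like list is higher in every array labelled knockout (difference 1.17), and the cytoskeleton list separates first from second arrays (second minus first -1.06).

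The genotypes were compared to ask which genes differ when Rex-1 is targeted. Genes of the two-cell-like state, a rare state of embryonic stem cells that resembles the early embryo, were higher as a list in the arrays labelled knockout. Of the 22 genes on the list, 19 were found in the gene table and 7 were measured. Of the other 12 found, 11 had no probe set of 1 symbol and 1 lay below the filter. All 7 measured members had a positive averaged value, with a mean log2 difference of 1.17 (1.06 with LIF and 1.29 without). Usp17la differed by 1.52 (SE 0.33), Tcstv1 by 1.07 (SE 0.29) and Tcstv3 by 2.96 (SE 0.86), and these 3 passed when adjusted over the list alone, at adjusted p from limma of 0.0286, 0.0353 and 0.0353. Tcstv1 and Tcstv3 had mean log2 levels of only 5.02 and 5.16. Zfp352 had a value of 1.03 (SE 0.37) and Eif1a 0.06 (SE 0.20), and neither passed. The list rose in the camera test at adjusted p = 4.83e-05, and with an estimated correlation the adjusted p was 0.681. The list mean was higher in all 4 knockout-labelled arrays than in all 4 J1 arrays (exact permutation p = 0.0286, two-sided, the smallest possible, and 0.219 adjusted over lists, with the same limit). With LIF the call was lost without the first J1 array or the first knockout-labelled array, over a range of 0.74 to 1.38. Without LIF the call was kept, and the difference was 0.75 without the first J1 array, over a range of 0.75 to 1.83. At a mean log2 floor of 8, chosen after the data were seen, 2 members were left and the list could not be tested.

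Germ cell genes that are usually silenced by DNA methylation also rose as a list in the arrays labelled knockout. The mean difference over 16 genes was 0.39, with 14 higher and 2 lower (camera adjusted p = 3.64e-05, and adjusted p = 0.681 with an estimated correlation). Tex101 differed by 1.45 (SE 0.20) on average and passed over the list alone (limma adjusted p = 0.00719), at a mean log2 level of 5.57. With LIF it differed by 2.65 (SE 0.28), so most of its averaged value came from the arrays with LIF. The values were 0.65 (SE 0.18) for Taf7l, 0.51 (SE 0.19) for Mael and 0.58 (SE 0.23) for Dazl, a germ cell RNA-binding protein, none of which passed. Without LIF the call of the list was lost without the first J1 array or the second knockout-labelled array, over a range of 0.13 to 0.41. With LIF the mean was 0.50, and 0.28 at the mean log2 floor of 8.

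Neural ectoderm genes were lower in the arrays labelled knockout, by a mean of -0.46 over 23 genes, with 16 lower and 7 higher (camera adjusted p = 0.000633, and adjusted p = 0.652 with an estimated correlation). Gap43, a growth cone protein, differed by -1.32 (SE 0.23) and passed over the list alone (limma adjusted p = 0.0363). Sox11 had a value of -1.07 (SE 0.41) and Pax6 -0.56 (SE 0.21). With LIF the list had a mean of -0.34, and that call was lost when any of the 4 arrays with LIF was left out and when all probe sets of a gene were averaged. Without LIF the mean was -0.58, and that call was lost without the first knockout-labelled array, over a range of -0.83 to -0.32, and at the mean log2 floor of 8, at -0.39 (adjusted p = 0.0728). The primed epiblast list had a mean of -0.28 (camera adjusted p = 0.00288, and adjusted p = 0.719 with an estimated correlation), with values of -1.11 (SE 0.26) for Cldn6, -0.85 (SE 0.27) for Sox4 and -0.55 (SE 0.16) for Dnmt3a. Its averaged call was lost without the first J1 array with LIF or the second knockout-labelled array without LIF, over a range of -0.40 to -0.16. With LIF alone it was lost without the first J1 array or the second knockout-labelled array, over a range of -0.50 to -0.03, and it was -0.43 at the mean log2 floor of 8. Without LIF it was lost when any of 4 arrays was left out, with a range of -0.46 to -0.13, and with the letter r as a replicate block (adjusted p = 0.0719). With all probe sets of a gene averaged, the call was lost with LIF (adjusted p = 0.196) and without LIF (0.0873) and kept on average (0.0291).

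Cytoskeleton and adhesion genes had an averaged difference of -0.59 over 32 genes, all 32 with a negative value (camera adjusted p = 1.31e-06, and adjusted p = 0.992 with an estimated correlation). This list differed more between first and second arrays (-1.06) than between genotypes. Its genotype difference was -0.995 in the first arrays and -0.19 in the second arrays. With LIF the difference was 0.04 without the first J1 array, and without LIF it was 0.23 without the first J1 array, so that 1 array set the direction in each. These calls were lost without the second knockout-labelled array, at -0.34 with LIF and -0.18 without it. The averaged difference was -0.21 and -0.25 without either first J1 array, and -0.98 and -0.94 without either second one. The 1 measured mitochondrial-encoded probe set was higher in the second array of every group, by 0.72 to 0.95 log2 units, and the 3' to 5' signal ratio of the Gapdh control was lower there, by 0.03 to 0.08. The same ratio of the Actb control was higher there in 3 groups, by 0.009 to 0.1, and differed by -0.003 in J1 cells without LIF. Fibroblast or feeder markers moved with this list, with which they share Acta2 and Tagln, so part of this is built in. The joint movement was not tested. The mean of the fibroblast or feeder markers was 0.51 and 0.44 in the first J1 arrays and between -0.37 and 0.10 in the other 6. Their genotype difference was -0.48 in first and 0.19 in second arrays. Flna had a value of -0.62 (SE 0.24) and Tpm1 -1.01 (SE 0.58), and 0 members passed over the list alone. Markers of other cell types did not pass for genotype: the mean difference was -0.15 for fibroblast or feeder markers (camera adjusted p = 0.661), 0.15 for extraembryonic endoderm (0.772) and -0.14 for trophoblast (0.986).

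No single probe set passed for genotype in limma. It called 0 of 43439 with LIF, 0 without LIF and 0 on average, and 2181, 1599 and 2291 had an unadjusted p under 0.05 against 2172 expected by chance. With a trended and robust prior 1 was called on average. In 18 settings chosen after seeing the data the counts ran from 0 to 122 on average, 0 to 12 with LIF and 0 to 8 without LIF. Without the letter r as a replicate block the highest were 3, 0 and 0. In these later settings, unadjusted p under 0.05 was also counted at a mean log2 floor of 10 without a trend. With the block it was reached by 936 of 6516 probe sets on average, 662 with LIF and 484 without LIF. Without the block the numbers were 356, 192 and 158. The uncalled probe sets of smallest p were mostly near the floor. They included Slfn8 (2.61, SE 0.22), Serpina3i (-3.17, SE 0.31) and Tex101 (2.65, SE 0.28) with LIF, Cab39l (2.81, SE 0.25), Nrk (-2.96, SE 0.28) and Gk2 (3.41, SE 0.34) without LIF, and Tnc (2.51, SE 0.16) and Spesp1 (3.23, SE 0.26) on average. The genotype differences with and without LIF correlated across probe sets at Pearson r = 0.0797 and Spearman rho = 0.124, with 57.1% of the same sign. Over the 6516 probe sets with a mean log2 of at least 10 the value was r = 0.551. The averaged genotype and LIF changes correlated at r = -0.0685 and rho = -0.0906.

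The interaction asked whether LIF withdrawal acts differently in the 2 lines. limma called 0 of 43439 probe sets, with 1543 at an unadjusted p under 0.05 and 2172 expected by chance, and camera called 0 lists. Rassf4 (-4.09, SE 0.37) and Cab39l (3.91, SE 0.36) were among the probe sets of smallest p and were not called. Chromosome by chromosome, the median difference between genotypes lay between -0.03 and 0.05, and 0 of 20 chromosomes passed (exact permutation, smallest p = 0.0286, smallest adjusted p = 0.571). With 4 arrays against 4 a chromosome passes only if most reach that p together, so this test could show little.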

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

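All tests in this part were chosen after the values were seen. The LIF response of 2 list members differed between the lines by the interaction in limma when adjusted over the list alone, and neither passed over all probe sets (adjusted p = 1 for both). Gsc, on the mesoderm list of 22 genes, had an interaction of 4.60 (SE 0.80, list-adjusted p = 0.0325), with -2.80 in J1 cells and 1.80 in the knockout-labelled cells at a mean log2 level of only 3.67. Tex101, on the germ cell list of 16 genes, had an interaction of -2.40 (SE 0.40, list-adjusted p = 0.0190), with 0.13 in J1 cells and -2.27 in the knockout-labelled cells at a mean log2 level of 5.57. At mean levels of 4 to 6, where Tex101 lies, replicate arrays differed by a median of 1.01 log2 units.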

How the results depend on the processing

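The 0 calls of the 7 contrasts held under each alternative fixed in advance, including the letter r as a replicate block, each array left out (the lone array then assumed to vary like the others), and also with control probe sets kept, except that a trended and robust prior called 1 probe set for the averaged genotype. After that, 18 settings were tried with the data in view, 9 of them with the replicate block, and every result is given here because choosing 1 would favour the largest count. The 9 settings without the block called 0 throughout, apart from 3 for the averaged genotype with log2 of at least 6 in 2 arrays and the trended, robust prior. With the block and mean log2 floors of 7, 8, 9 and 10, the averaged genotype had 2, 23, 40 and 38 calls, and 95, 122, 94 and 75 with the trended, robust prior added. The averaged LIF contrast had 0, 0, 9 and 6, and 21, 22, 24 and 15. Genotype with LIF had 0, 3, 6 and 2, and 6, 12, 8 and 5. Genotype without LIF had 0, 4, 4 and 4, and 8, 8, 7 and 6. With the block and log2 of at least 6 in 2 arrays, and in both single-line LIF contrasts and the interaction in all 18, calls were 0. The cause was not tested. The block is not a planned pairing: correlations of second-minus-first differences were 0.0497 to 0.198 on the planned probe sets, and 0.318 to 0.771 at a floor of 10, a value seen together with these calls.

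Of 161 list tests, 23 were called with the preset correlation and 0 with an estimated one. The number was 18 with probe sets averaged, 22 with the block, 23 with quantile normalization and 18 to 28 with 1 array left out. An estimated correlation could raise p even where it lay below the preset 0.01. For the averaged genotype the neural ectoderm list had an estimated correlation of -0.027, and its unadjusted camera p went from 4.72e-05 to 0.0109. A call lost this way is therefore no evidence by itself of correlated genes. The other called lists had estimates above the preset value. These were 0.574 for cytoskeleton, 0.316 for two-cell-like, 0.158 for germ cell, 0.085 for LIF, 0.080 for primed epiblast and 0.038 for pluripotency genes. For these lists the preset p-values assume a lower correlation than the estimated one. A mean floor of 8 left 19 lists and 133 tests, with 23 calls, of which 19 were among the first 23 and 4 were not. The 3 two-cell-like calls could not be tested there, and neural ectoderm without LIF was lost. With 1 array left out, the cytoskeleton list ranged from -1.33 to 0.0444 with LIF and from -1.32 to 0.233 without LIF, the positive values without the first J1 array. Zfp42 kept its direction and stayed uncalled, at -0.12 with quantile normalization and -0.30 to -0.13 with 1 array left out. The smallest adjusted p over chromosomes moved from 0.571 to 0.286 with the stricter filter, and 0 passed in both. Without a filter the 3 correlations across probe sets were 0.0772, 0.0136 and -0.0693 against 0.0797, 0.0151 and -0.0685. The probe sets of smallest p kept their directions with quantile normalization, the trended and robust prior and each array left out. This is no test, because they were picked for small p in these same arrays, and the prior leaves the fitted change as it is. Low values carry an unknown share of background. The alternative of fitting only the groups in a contrast does not apply to the interaction and averages.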

Other observations

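All tests in this part were written down after the values they measure had been seen. In the 18 settings tried after seeing the data, some genes not on the lists were called repeatedly for the averaged genotype, nearly always with the letter r as a replicate block. Xist, the RNA of the X inactivation centre, was called in 5 of the 7 settings that tested it with the block and 1 of the 7 without, with a log2 difference of -1.46 (SE 0.20) and an adjusted p of 0.564 in the planned fit. Ak4, an adenylate kinase, was called on 1 of its probe sets in 7 of 9 settings with the block and 0 of 9 without, with 0.77 (SE 0.15) and a planned adjusted p of 0.714. Other Ak4 probe sets were called with the block in 6 of 9 settings (0.85, SE 0.20) and in 1 of 5 (0.78, SE 0.21). For LIF withdrawal, Spink1 was called in 4 of 7 settings with the block and 0 of 7 without (-1.33, SE 0.19, planned adjusted p = 0.700). Fblim1 was called on 1 of its probe sets in 6 of 9 with and 0 of 9 without (-0.86, SE 0.23, planned adjusted p = 0.9999). Another Fblim1 probe set was called in 5 of 9 with the block (-0.75, SE 0.18). None of these passed the planned test, and they were chosen after their values were seen. Members of the fixed lists were also called with the block, and never without it. For LIF withdrawal they included Socs3 (6 of 9 settings on 1 probe set, 1 of 9 on another), Pim3 (6 of 9 and 4 of 9), Dnmt3a (5 of 9), Icam1 (4 of 7) and Bcl3 (3 of 7). For genotype they included Sox4 and 1 Dnmt3a probe set (6 of 9 each), Sox11 (5 of 7), Usp17la and Gap43 (3 of 5 each). In the planned fit none passed over all probe sets.

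Other splits of the 8 arrays into 4 and 4 were fitted as 2 groups, 35 in all. For the averaged genotype contrast the real split called 3 probe sets and 2 of the 35 splits called as many, the real one and the letter r, which called 6. The remaining splits called at most 2, and with the letter as a block the planned fit called 0. A share of 2 in 35 is not under 0.05, but the other split is the letter r, a labelled grouping of the arrays. The share therefore could not decide on chance, which was not excluded. For the averaged LIF contrast the real split called 0, so all 35 splits called as many. To allow for the search, the highest count over the 18 settings was taken in each split. Genotype reached 160 and LIF 28. The split of first against second arrays, which only the settings without the block can fit, reached 2610, many times either real count, which points to a structure of the arrays that follows the letter r. As many as the real count were reached by 2 splits for genotype, the real one and the letter r, and by 3 for LIF, the real one, genotype and the letter r. The remaining splits reached at most 4. Neither share is under 0.05, but the matching splits follow the letter r or genotype, which are labelled groupings of the arrays. This measure therefore could not decide on chance, which was not excluded. The list tests called 5 lists for genotype, as many as in 9 of the 35 splits, and 3 for LIF, as many as in 16, with 7 as the highest other in both. The number of lists called with the preset correlation is thus no evidence by itself. The LIF list was strongest in the real LIF split (-log10 p of 12.65 against 5.96 for the highest other, 1 of 35). The two-cell-like list was strongest in the real genotype split (6.17 against 4.54, 1 of 35). Both ranks were taken up after the values were seen, so they do not exclude chance. The two-cell-like list was moreover singled out among 23, whereas the LIF list was fixed beforehand as the list about LIF. With the strongest of the 23 lists taken in each split, the real value was 8.95 for genotype, reached in 8 of the 35 splits, and 12.65 for LIF, reached in 3, with 14.98 as the highest other in both, so chance was not excluded. In the other splits that reached 12.65 the cytoskeleton list was the strongest, and the LIF list had a camera p of 0.0579 and 4.15e-06.

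The second arrays deviated together from the first arrays. Hybridisation and scanning are a candidate explanation. The spiked hybridisation controls, which do not come from the cells, were 0.435 log2 units higher on average in second arrays, but the difference was 0.84, 0.57 and 0.35 in 3 groups and -0.02 in the knockout-labelled cells without LIF. Of the measures that come from the cells, the mitochondrial-encoded probe set was higher in second arrays by 0.93, 0.95, 0.85 and 0.72 and the Gapdh 3' to 5' ratio was lower in all 4 groups, whereas the Actb ratio differed by 0.1, -0.003, 0.043 and 0.009. Array handling and a second round of cell culture cannot be told apart here, because the labels do not say what the letter r marks.

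The mean of the 7 measured two-cell-like genes was higher in the arrays labelled knockout. A difference between first and second arrays that is alike in all groups cancels from this comparison, since each group has 1 of each. The list shifted by 1.40 in first arrays alone and 0.942 in second arrays alone. Positive shifts in both follow from the separation of the arrays reported above, so they are no further test. Noise near the floor stays open: the members with a mean log2 of at least 8 shifted by 0.789, but these are only Usp17la and Eif1a, which moved by 1.52 and 0.06. Probe sets that read several near-identical genes could also make members move as 1. Of the measured members 14.3% lie on a probe set whose suffix marks several transcripts, which is that of Eif1a (0.06), and the 6 members that differed more lie on probe sets without that mark. Probe sets with several gene symbols had been left out of the list tests beforehand, so the missing mark decides nothing. No probe sequences were used, so this stays open. An effect of genotype and a difference between clones, which this design confounds, were not tested.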
